A study of Mus musculus with 4 samples.

How the data were processed

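H3K4me3 chromatin immunoprecipitation sequencing (ChIP-seq) was measured in 4 libraries of gastrocnemius from adult female B6CASTF1/J mice aged 2 months. Per the labels, the libraries came from 2 pools, E (biological replicate 1) and F (biological replicate 2), each made from 2 biosamples and sequenced as technical replicates 1 and 2, with fragments of 200 to 600 bp. All 4 libraries belonged to the same tissue, sex, age and strain, so no contrast between conditions existed.

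The 4 deposited lists were narrowPeak files on mm10. Per the deposited text file of each sample, peaks had been called on the filtered alignments of pool E, of pool F and of both pools. The lists of pool E, of pool F and a pooled list were pseudoreplicated peaks, and another list of both pools held replicated peaks. The 2 technical libraries of a pool shared 1 alignment, so no list held a value per library. A further input, the same for every list, was named there without a description. The aligner, the peak caller and their settings were not given in the sources used here. The deposited signal value of each peak was the authors' own, and what it is relative to was not stated, so it served only to describe, rank or filter peaks within a list. In the deposited narrowPeak files the significance columns held the −log10 p-value and the −log10 q-value of each peak. The lowest −log10 p-value in the replicated list was 2.03 and the lowest −log10 q-value 0.364, and 478 of its deposited peaks (1.14%) had a q-value above 0.05. The lists hold no read counts, so the depth of each library and pool is unknown.

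Genes and transcription start sites (TSSs) came from GENCODE M21, and sequences from the RefSeq assembly GRCm38.p6, the same build as mm10. The background held 21755 protein-coding genes on the 19 autosomes and X, with 93196 TSSs, and all annotated genes had 130677 TSSs there. A gene was called marked when a peak lay within 1000 bp of any of its TSSs, and its signal value was the highest of those peaks. Peaks separated by at most 1000 bp were joined into domains, and a gene's domain width was that of the widest domain within 1000 bp of its TSSs. A gene's signal value and domain width could thus come from different TSSs, as for Myl3, Pfkm, Mylk, Gsn and Tef, among others. Each gene was put in a CpG class from windows of 1000 bp at its TSSs. The high class needed an observed over expected CpG ratio of at least 0.75 and a GC content of at least 55%, the low class needed ratios under 0.48 in all windows, and other genes were intermediate.

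The share of peaks near TSSs was set beside 100 shuffles that moved each peak to a random place of its chromosome. Intervals given for shares are 95% Wilson intervals, which cover counting error only. Overlap between the pools needed 1 bp or more. A total of 25 gene lists with 340 entries (338 distinct genes) was fixed, covering fast fibre, slow fibre, sarcomere and triad, developmental muscle, myogenic transcription factor and fusion, satellite cell, neuromuscular junction, fibroblast and fibro-adipogenic progenitor, tendon cell, endothelial, smooth muscle and pericyte, macrophage, lymphocyte, Schwann cell, adipocyte, neuron, hepatocyte, cardiac, germ cell and pluripotency, limb position, oxidative phosphorylation and citrate cycle, glycolysis and glycogen, clock, muscle mass and metabolism, and housekeeping genes. Aldoa was left out of the glycolysis list because 2 protein-coding genes carry that name. The share of marked genes of each list was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. The median domain width of each of the 21 lists with at least 5 marked genes was compared with 10000 random lists of as many marked genes by a two-sided permutation test, whose smallest possible p is 0.0002. Genes marked in pool E only and in pool F only were compared by a two-sided exact binomial test against the split over all genes. P-values were adjusted over the lists of each test by the Benjamini-Hochberg method with a threshold of 0.05. Marked shares of X-linked, autosomal and CpG-class genes were compared by 6 two-sided Fisher's exact tests, adjusted together. Genes are not replicates, so these tests describe the deposited lists and not a population of mice.

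The gene lists, the tests, the thresholds and the rule for named genes were set before the data were examined. The rule took, for each list, up to 4 marked members with the highest signal value and up to 4 unmarked members in alphabetical order. It also took the 12 genes with the widest domains, the 10 with the highest signal value, the 5 with the highest signal value among those marked in each pool only, the 5 peaks with the highest signal value over 5000 bp from any TSS, and Xist. Some genes that the rule took are not reported here. A permutation test of domain width between fast and slow fibre genes, with 100000 resamples, was added after the data had been seen.

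Alternatives were a TSS window of 0 or 2500 bp, TSSs of all annotated genes, a −log10 q-value of at least 10, the pooled list, the list of either pool alone, an overlap of 50% of the peak or of both peaks, joining over 0 or 3000 bp, and backgrounds matched on CpG class. For the marking of gene lists, the matched background used a two-sided exact test stratified by CpG class in place of Fisher's. It drew a list's genes at random within their classes. The share of other genes was weighted by the list's classes. Chromosome Y was left out of gene tests because the animals were female. Copies of TSS windows and of chromosome Y peaks elsewhere in the assembly were searched with blastn 2.17.0. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The code was tested on simulated data on the 21755 genes. It returned 1020 of 1020 overlap and gene calls as a base-by-base count did. It recovered 200 of 200 lists of 15 genes with altered marking and called 5 of 300 unaltered lists. It recovered 25 of 25 lists widened 3 times, calling 2 of 75 others, and the 1 list made specific to pool E, calling 0 of 1 other.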

Results

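H3K4me3, a histone mark of promoters, was mapped by ChIP-seq in gastrocnemius, the large muscle of the calf, of adult female B6CASTF1/J mice, first-generation hybrids of the C57BL/6J and CAST/EiJ strains. The 4 libraries formed 2 pools, E and F, with 2 technical libraries each. The replicated list held 41955 peaks that covered 57.9 Mb, with a median width of 876 bp (interquartile range 459 to 1876 bp) and a median signal value of 7.64 (3.93 to 34.4). The list of pool E held 42418 peaks over 60.6 Mb, that of pool F 39544 peaks over 52.9 Mb and the pooled list 45270 peaks over 58.9 Mb. Depth is unknown for all lists. With 1 tissue and 1 condition, the comparisons set the pools, the regions and the gene groups against each other.

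The pools shared nearly all marked promoters. Of the protein-coding genes marked in at least 1 pool, 98.7% were marked in both: 14930 genes in both pools, 136 in pool E only, 54 in pool F only and 6635 in neither. Among genes marked in both were the muscle creatine kinase gene Ckm, the fast myosin light chain gene Mylpf, the desmin gene Des and the endothelial receptor gene Flt1. The median signal value in pool E was 4.10 for genes of that pool only and 49.1 for shared genes, and in pool F it was 3.46 and 42.9.

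The genes marked in pool E only with the highest signal values were Foxh1 (56.0), Foxq1 (46.6), Hist1h1d (43.4), Astl (37.2) and Adam8 (31.3). Foxh1 and Foxq1 encode forkhead transcription factors, Hist1h1d a linker histone, and Astl and Adam8 metalloproteases. For all 5 the pool E peak was overlapped by a pool F peak, and the 1000 bp window separated them: the pool E peak near Foxh1, on chromosome 15 from 76670945 to 76672714, lay 997 bp from a TSS and the nearest pool F peak 1004 bp. The nearest pool F peak lay 1110 bp from Foxq1, 1114 bp from Hist1h1d, 1136 bp from Astl and 1018 bp from Adam8. Of the 136 genes, 16 had such an overlapped peak, with a median signal value of 15.3, and the other 120 had a median signal value of 4.07 with a maximum of 7.28. Marked in pool F only with the highest signal values were Zxdb (5.85), a zinc finger gene, Cd86 (5.51), a co-stimulatory receptor gene of antigen-presenting cells, Gsg1 (5.48), Amt (5.34), a gene of glycine cleavage, and Pcdhb6 (5.34), a protocadherin gene. The Gsg1 peak was overlapped in pool E.

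No gene list, cell type markers included, passed the test between the pools: 0 of 25 did in the two-sided exact binomial test, each with an adjusted p of 1, and 0 had an unadjusted p under 0.05. The members marked in pool E only included Cd22 and Zap70 of the lymphocyte list, Cdh19 of the Schwann cell list, Gad1 of the neuron list and Apoa1 of the hepatocyte list. Cdh19 and Zap70 were singled out after their values were seen. With at most 2 such genes in a list, the test could not pass its threshold.

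By peaks, 35010 of 42418 pool E peaks (82.5%, 95% Wilson interval 82.2 to 82.9%) were overlapped in pool F, and 37103 of 39544 pool F peaks (93.8%, 93.6 to 94.1%) in pool E. The pools shared 50.9 Mb, which was 83.9% of the sequence under pool E peaks and 96.2% of that under pool F peaks. When the peaks of a pool were put in 10 classes of equal size by signal value, the class with the lowest values was overlapped in 32.1% of pool E peaks and 71.7% of pool F peaks. In the 4 highest classes of each pool every peak was overlapped. The replicated list left out 4665 peaks of the pooled list, which had a median signal value of 2.89 and a median width of 256 bp. Of these left-out peaks, 66.9% overlapped a pool E peak and 6.54% a pool F peak. The replicated list also held 1350 peaks without an identical position in the pooled list. Of all replicated peaks, 91.2% overlapped a peak in the list of pool E and 88.4% one in the list of pool F.

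**Figure D1:**
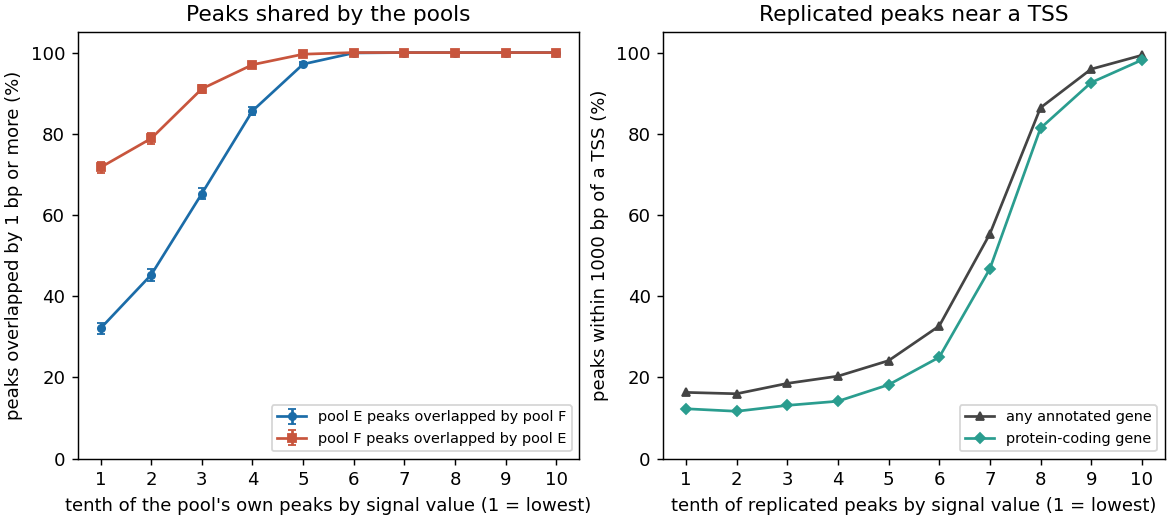
The left panel plots the percent of a pool's peaks overlapped by at least 1 bp in the other pool, with 95% Wilson intervals, and the right panel the percent of replicated peaks within 1000 bp of a TSS, each over 10 classes of the list's own signal value. Overlap rises from 32.1% in pool E and 71.7% in pool F to 100% in the highest class, and nearness to a TSS of any gene from 16.3% to 99.3%.

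Strong H3K4me3 peaks lay at promoters and weak peaks mostly elsewhere. Of the replicated peaks on the autosomes and X, 17343 (41.3%) lay within 1000 bp of a protein-coding TSS, against 6.23% on average in shuffled places (range of 100 shuffles 6.0 to 6.46%). With TSSs of all genes the number was 19511 (46.5%, shuffled mean 9.89%), and these peaks had a median width of 1864 bp and a median signal value of 35.6. A further 2951 peaks (7.03%, shuffled mean 8.41%) lay in exons, 11837 (28.2%, shuffled mean 33.3%) in introns and 7654 (18.2%, shuffled mean 48.4%) between genes. Intron peaks had a median width of 535 bp and a median signal value of 4.12. From the lowest to the highest signal class the share near any TSS went from 16.3 to 99.3% and the median width from 337 to 2597 bp.

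The promoters with the highest signal values in the replicated list were those of Gatad2a (64.1), a subunit of a chromatin remodelling complex, Kdm5c (64.0), an X-linked H3K4 demethylase, Dcaf12 (63.9), a ubiquitin ligase adaptor, and Clns1a (63.8), a factor of spliceosome assembly. Next came Bloc1s6 (63.7), a lysosome biogenesis factor, the vesicle fusion gene Vamp2 (63.7), the zinc finger gene Zkscan1 (63.6) and 1810049J17Rik (63.5). Elf1, an ETS transcription factor gene, and Wbp4 shared a domain at 63.6. The Gatad2a domain ran over 4577 bp, on chromosome 8 from 69970548 to 69975124.

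In gastrocnemius, 15067 of the 21755 protein-coding genes (69.3%) were marked, and the share differed by promoter CpG class. Marking, a high or intermediate class and domain width could each come from any TSS of a gene. The number of TSSs per gene was not matched here or in the gene list tests. Of high CpG genes 6797 of 6843 (99.3%) were marked, of intermediate genes 6164 of 6564 (93.9%) and of low CpG genes 2106 of 8348 (25.2%). High and intermediate genes differed by a two-sided Fisher's exact test (adjusted p = 1.26e-76), and intermediate and low genes had an odds ratio of 45.7, with a p too small to compute. Median domain width was 2792 bp in the high, 2109 bp in the intermediate and 1732 bp in the low class. Outside protein-coding genes, 1186 of 5305 lincRNA genes (22.4%), 1222 of 2958 antisense genes (41.3%), 405 of 2196 miRNA genes (18.4%) and 299 of 9849 processed pseudogenes (3.04%) were marked. Among those over 5000 bp from any protein-coding TSS, 741 of 4586 lincRNA genes (16.2%), 196 of 1335 antisense genes (14.7%) and 100 of 1478 miRNA genes (6.77%) were.

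X-linked genes were marked less often than autosomal genes. Of X-linked genes 499 of 948 (52.6%) were marked and of autosomal genes 14568 of 20807 (70.01%), with an odds ratio of 0.476 (two-sided Fisher's exact test, adjusted p = 1.33e-27). In the intermediate CpG class the shares were 86.7 and 94.3% (Fisher's exact test, adjusted p = 4.07e-06). Those in the high class were 99.2 and 99.3% (Fisher's exact test, adjusted p = 0.555) and those in the low class 22.7 and 25.4% (Fisher's exact test, adjusted p = 0.214). Near-identical copies of their TSS windows existed for 186 X-linked genes, of which 14 (7.53%) were marked. Of these genes, 163 were in the low CpG class, with 1 marked. Copies existed for 986 autosomal genes, of which 20.5% were marked. Of the 762 X-linked genes without a copy 63.6% were marked (95% Wilson interval 60.2 to 67.0%). At the shares of autosomal genes without a copy of the same CpG classes, 63.4% would have been. The classes differed in opposite directions, which offset each other in these overall shares. Among genes without a copy, X-linked genes of the intermediate class were marked less often (odds ratio 0.433, two-sided Fisher's exact test, adjusted p = 0.000319). In the low class 32.6% of X-linked and 27.6% of autosomal genes without a copy were marked (Fisher's exact test, adjusted p = 0.0623). These comparisons of genes without a copy were added after the data had been seen. Xist, the non-coding RNA gene expressed from the inactive X, had a peak of 3858 bp from 103480409 to 103484266 with a signal value of 48.0. The Xist peak was 3951 bp wide in pool E and 3844 bp in pool F.

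Every gene was marked in 14 of the 25 lists, among them lists of contractile fibre, vessel and energy metabolism genes. All 16 fast fibre, 12 slow fibre, 28 sarcomere and triad, 15 endothelial, 15 fibroblast and fibro-adipogenic progenitor, 12 satellite cell and 15 glycolysis and glycogen genes were marked, against 69.2% of other genes. Of the 25 lists, 12 were marked more often than other genes, 2 less often and 11 neither, by two-sided Fisher's exact tests. Values given with the genes of these lists are signal values in the replicated list.

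Among fast fibre genes (Fisher's exact test, adjusted p = 0.0169), the highest signal values were at Mylpf (58.8), Actn3 (57.7), the fast-fibre alpha-actinin gene of the Z-disc, Eno3 (55.7), the muscle enolase gene, and Ckm (53.1). Among slow fibre genes (Fisher's exact test, adjusted p = 0.0416) they were at Atp2a2 (51.0), the calcium pump gene of slow and cardiac muscle, Tpm3 (50.6), a slow tropomyosin gene, Tnnc1 (46.8), slow and cardiac troponin C, and Myl3 (36.9), a slow myosin light chain gene. Atp2a2 and Tpm3 were the 2 high CpG genes of the slow list, whose median signal value was 10.1. Sarcomere and triad genes (Fisher's exact test, adjusted p = 0.000561) were led by Tpm1 (53.0), a tropomyosin gene, Des (50.8), and the Z-disc genes Ldb3 (49.8) and Tcap (49.6). Of 8 developmental muscle genes 4 were marked (Fisher's exact test, adjusted p = 0.310): the embryonic and atrial light chain gene Myl4 (55.6), Ncam1 (39.3), the growth factor gene Igf2 (27.0) and the cardiac actin gene Actc1 (9.07). The unmarked members were the fetal acetylcholine receptor subunit gene Chrng, the embryonic and perinatal myosin genes Myh3 and Myh8, and Tnnt2, cardiac troponin T.

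Of the 13 myogenic transcription factor and fusion genes 11 were marked (Fisher's exact test, adjusted p = 0.383). Mef2a (59.9), Mef2d (57.6) and Six4 (51.8), all transcription factor genes of muscle, were among the highest, and the myoblast fusion genes Mymk and Mymx were unmarked. Satellite cell genes (Fisher's exact test, adjusted p = 0.0416) were led by the proteoglycan gene Sdc4 (47.7), the signalling inhibitor gene Spry1 (44.4), the laminin receptor gene Itga7 (43.2) and Cdh15 (38.5), M-cadherin. At the neuromuscular junction 10 of 11 genes were marked (Fisher's exact test, adjusted p = 0.238), led by Etv5 (56.4), Lrp4 (48.9), the agrin receptor gene, Chrnb1 (37.7) and Dok7 (36.5). Chrnd, a receptor subunit gene, was unmarked.

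Genes of other cell types in muscle were marked as well. Fibroblast and fibro-adipogenic progenitor genes (Fisher's exact test, adjusted p = 0.0193) were led by Cd34 (41.0), Gsn (39.2) and the collagen genes Col1a1 (35.3) and Col1a2 (35.0). Endothelial genes (Fisher's exact test, adjusted p = 0.0193) were led by Egfl7 (47.5), the VEGF receptor gene Flt1 (38.6), the tight junction gene Cldn5 (38.0) and Sox18 (35.6). All 8 tendon cell genes (Fisher's exact test, adjusted p = 0.159), with the tendon transcription factor genes Mkx (42.4) and Scx (38.3), Thbs4 (23.0) and Comp (13.2), were marked. So were all 10 smooth muscle and pericyte genes (Fisher's exact test, adjusted p = 0.0627), with the channel subunit genes Abcc9 (34.1) and Kcnj8 (24.4), Cspg4 (29.7) and Mylk (20.0). Of 12 macrophage genes 11 were marked (Fisher's exact test, adjusted p = 0.159) at weak peaks, the highest being those of the growth factor receptor gene Csf1r (8.02), the complement gene C1qc (7.16), Cd163 (6.40) and Tyrobp (6.31), with Cx3cr1 unmarked. At a TSS window of 0 bp 50% of the macrophage genes were marked. Of 10 Schwann cell genes 9 were marked (Fisher's exact test, adjusted p = 0.342), with the myelin genes Prx (48.0), Pmp22 (43.8) and Mbp (39.2) among the highest.

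Adipocyte genes were split, with 5 of 11 marked (Fisher's exact test, adjusted p = 0.154). Lipe (55.4), a lipase gene, Plin4 (45.7), Pparg (45.7) and Fabp4 (29.5) were marked, and the adipokine genes Adipoq and Lep, with Cfd and Cidec, were unmarked. Of 12 lymphocyte genes 3 were marked, fewer than among other genes (Fisher's exact test, adjusted p = 0.0102): the kinase gene Lck (37.5), Pax5 (14.9) and Cd79b (3.17), the last of which was marked in neither pool's own list. Against genes of the same CpG class, of which 42.9% were marked, the lymphocyte call was lost (exact test stratified by CpG class, adjusted p = 0.217). The T cell receptor complex genes Cd3e and Cd3g and the B cell gene Cd22 were unmarked. Of 14 hepatocyte genes 1 was marked, again fewer (Fisher's exact test, adjusted p = 5.44e-05), a call lost against the same CpG class, of which 25.3% were marked (stratified exact test, adjusted p = 0.296). It was the apolipoprotein gene Apoa1 (24.5), whose peak in pool E lay 933 bp from a TSS and whose nearest peak in pool F lay 1017 bp away. Without replicate 1, or at a TSS window of 0 bp, 0 hepatocyte genes were marked, and at 2500 bp 14.3% were. Albumin (Alb), Ahsg, Apoa2 and Cps1 were unmarked.

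Of 12 neuron genes 9 were marked (Fisher's exact test, adjusted p = 1), led by Elavl4 (25.1), Nefm (21.3), Slc17a7 (17.9) and Stmn2 (11.2), while Gad1, Slc17a6 and Snap25, of transmitter synthesis, transport and release, were unmarked. Of 11 cardiac genes 6 were marked (Fisher's exact test, adjusted p = 0.359), led by Hcn4 (38.5), the transcription factor genes Gata4 (31.7) and Hand2 (27.7), and Ryr2 (13.0). Myh6, Myl7, Nkx2-5 and Nppa, genes of heart muscle, were unmarked. Of 11 germ cell and pluripotency genes 4 were marked (Fisher's exact test, adjusted p = 0.0661): Dazl (34.3), Utf1 (12.01), Dppa3 (6.31) and Lin28a (3.14). The unmarked members included Ddx4, Mael, Nanog and Pou5f1. Against genes of the same CpG class, of which 82.9% were marked, germ cell and pluripotency genes were marked less often (stratified exact test, adjusted p = 2.49e-05). With that background macrophage genes (25.1% of others marked, stratified exact test, adjusted p = 1.97e-05) and smooth muscle and pericyte genes (45.8%, adjusted p = 0.000296) were marked more often. So were tendon cell genes (68.8%) and neuromuscular junction genes (63.2%), with an adjusted p of 0.0457 each in the stratified exact test.

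All members of the other 6 lists were marked. Limb position genes (16 genes, Fisher's exact test, adjusted p = 0.0169) were led by the homeobox genes Hoxc10 (55.3), Hoxd9 (54.8), Hoxc9 (45.9) and Hoxd10 (37.8). Oxidative phosphorylation and citrate cycle genes (20 genes, Fisher's exact test, adjusted p = 0.00617) were led by Ndufv1 (61.9), Ogdh (58.1), Cox5b (54.3) and Ndufa9 (52.9). Glycolysis and glycogen genes (Fisher's exact test, adjusted p = 0.0193) were led by Pfkm (61.4), muscle phosphofructokinase, Ldha (60.7), Eno3 (55.7) and Pkm (55.3). Clock genes (12 genes, Fisher's exact test, adjusted p = 0.0416) were led by Nr1d2 (60.9), Clock (58.8), Cry1 (57.1) and Tef (54.6). Muscle mass and metabolism regulators (15 genes, Fisher's exact test, adjusted p = 0.0193) were led by Fbxo32 (61.9), the atrophy ubiquitin ligase gene, Klf15 (61.0), Igf1r (59.1) and Ppargc1b (58.8). Housekeeping genes (21 genes, Fisher's exact test, adjusted p = 0.00493) were led by Reep5 (62.6), Actb (61.4), Rab7 (61.2) and Vcp (60.8). Against genes of the same CpG class the calls for the limb position, oxidative phosphorylation, clock, muscle mass and housekeeping lists were also lost. The slow fibre and limb position calls were also lost at a TSS window of 0 bp or a −log10 q-value of at least 10, and the satellite cell and fibroblast calls at 0 bp. At 0 bp 83.3% of slow fibre, 91.7% of satellite cell and 93.3% of fibroblast and fibro-adipogenic progenitor genes were marked.

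The median H3K4me3 domain of marked fast fibre genes was 12511.5 bp, of myogenic transcription factor genes 8306 bp, of sarcomere and triad genes 8091 bp, of endothelial genes 7836 bp, of glycolysis and glycogen genes 7051 bp, of fibroblast and fibro-adipogenic progenitor genes 6469 bp and of muscle mass and metabolism regulators 5688 bp. None of 10000 random lists of marked genes reached any of these medians, and the random lists centred near 2402 bp (two-sided permutation test, adjusted p = 0.0006 for each, from the smallest p that 10000 lists could give). Of the 21 lists tested, 13 were wider than random lists, 1 was narrower and 7 were neither.

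Also wider were satellite cell genes (5600 bp, permutation test, adjusted p = 0.00157), smooth muscle and pericyte genes (5115 bp, adjusted p = 0.0042), clock genes (4437 bp, adjusted p = 0.00916) and housekeeping genes (3938 bp, adjusted p = 0.00462). Tendon cell genes (4322.5 bp) and oxidative phosphorylation and citrate cycle genes (3402.5 bp) were wider with an adjusted permutation p of 0.0375 each. Neuron genes were narrower at 1466 bp (permutation test, adjusted p = 0.0297). Slow fibre genes (2708.5 bp, permutation test, adjusted p = 0.577), neuromuscular junction genes (2504.5 bp, adjusted p = 0.901), macrophage genes (2414 bp, adjusted p = 0.972) and limb position genes (2892.5 bp, adjusted p = 0.302; 5460 bp and wider with joining over 3000 bp) did not pass the test. Nor did Schwann cell genes (3408 bp, permutation test, adjusted p = 0.15), adipocyte genes (4912 bp, adjusted p = 0.0515) and cardiac genes (1494.5 bp, adjusted p = 0.0551). The satellite cell (3021.5 bp), smooth muscle (3360 bp) and tendon (2546 bp) calls were lost when only touching peaks were joined, which also gave medians of 5073 bp for endothelial and 2023 bp for Schwann cell genes, and the tendon, oxidative phosphorylation and clock calls when joining reached 3000 bp. The tendon call was also lost without replicate 2, and the oxidative phosphorylation call without replicate 1 or with random lists matched on CpG class.

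**Figure D2:**
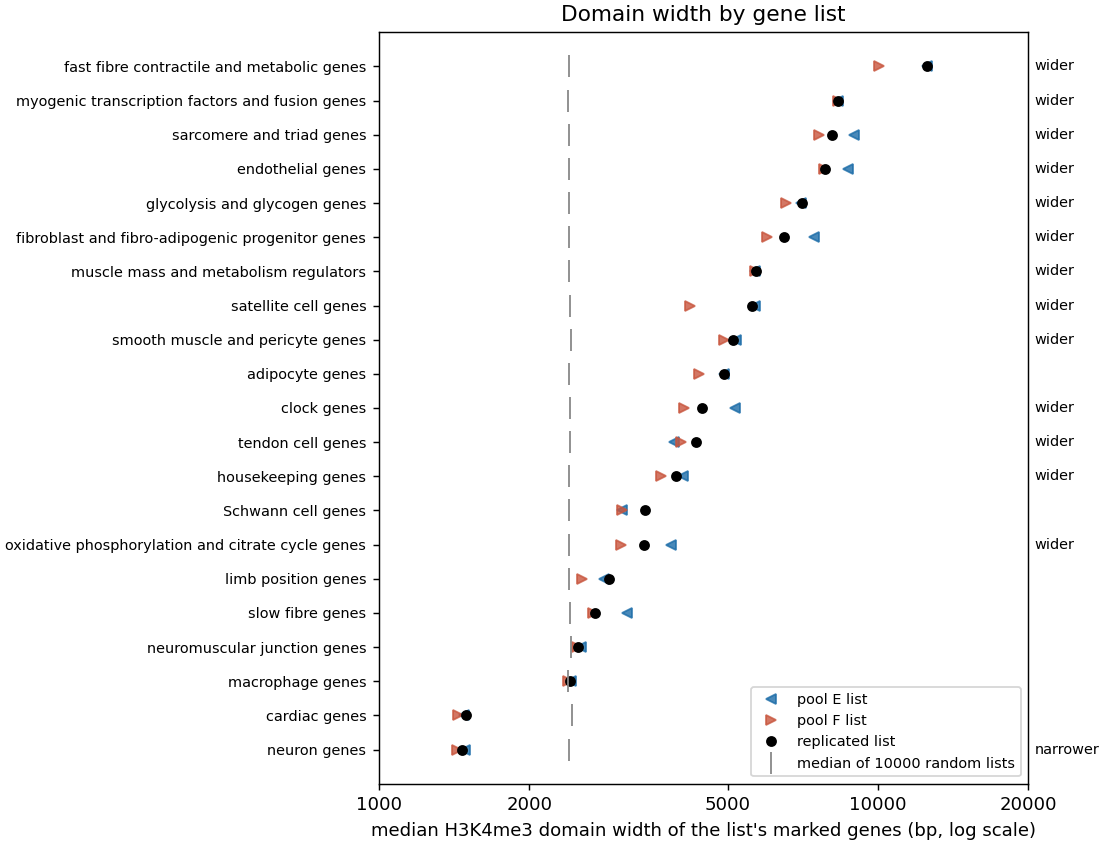
Each line is a gene list, and the horizontal log axis gives the median H3K4me3 domain width in bp of its marked genes in the replicated list (circles), in pool E and in pool F (triangles), with the median of 10000 random lists as a grey bar and the call of the permutation test at the right. Fast fibre genes lie at 12511.5 bp and neuron genes at 1466 bp, on either side of the random medians near 2402 bp.

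Fast fibre genes had wider domains than slow fibre genes. The medians were 12511.5 bp for the 16 fast genes (range 4961 to 24733 bp) and 2708.5 bp for the 12 slow genes (624 to 8411 bp), a difference of 9803 bp (two-sided permutation test, p = 6e-05). This test was chosen after the data had been seen. Without replicate 1 the difference was 7353 bp, and without replicate 2 it was 9399 bp. Ckm had a domain of 13119 bp on chromosome 7 from 19408675 to 19421793, which was 13044 bp wide in pool E and 8736 bp in pool F. The Eno3 domain on chromosome 11 from 70645151 to 70663136 was 17986 bp wide, with 18193 bp in pool E and 11784 bp in pool F. Mylpf (9478 bp, 9684 bp in pool E and 9328 bp in pool F) and Actn3 (9663 bp, 11483 and 9630 bp) varied less. Among slow genes, Atp2a2 had 7326 bp, Tpm3 7246 bp, Tnnc1 4310 bp and Myl3 2968 bp, the last at another TSS than its highest signal value. Of the adult myosin heavy chain genes, singled out after their values were seen, the fast-type Myh4 had 12030 bp, Myh2 5206 bp and Myh1 4961 bp. Their signal values were 23.2, 9.83 and 9.98. The slow-type Myh7 had 1233 bp at a signal value of 3.06.

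**Figure D3:**
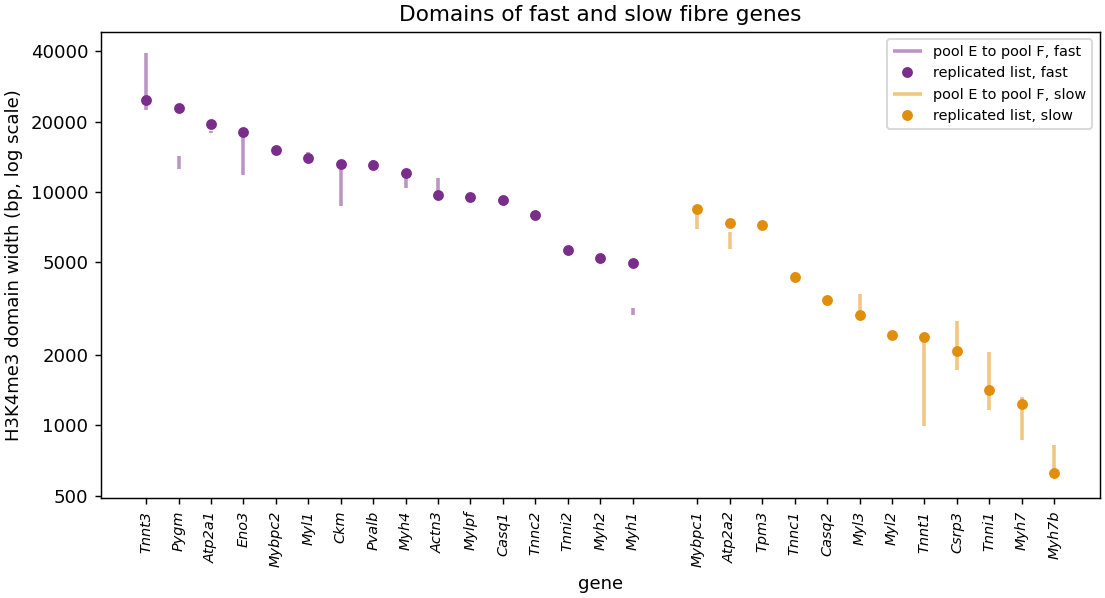
The vertical log axis gives the H3K4me3 domain width in bp of each fast fibre gene (left) and slow fibre gene (right), with a circle for the replicated list and a line between the widths in pools E and F. The fast genes lie between 4961 and 24733 bp and the slow genes between 624 and 8411 bp.

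The 12 protein-coding genes with the widest domains shared 8 domains. Pde4dip, which encodes myomegalin, had the widest at 32642 bp, on chromosome 3 from 97793389 to 97826030. The limb and trunk patterning genes Hoxc5, Hoxc9, Hoxc10 and Hoxc11 were credited with the same 31600 bp on chromosome 15 from 102952849 to 102984448. Any TSS of a gene counted, and the highest peak credited to Hoxc5 was that of Hoxc10, from 102958742 to 102969478. The domain thus need not cover the whole Hoxc5 gene. In pools E and F the domain of Hoxc10 was 20433 and 20506 bp wide, and that of Hoxc9 9422 and 9400 bp. Kmt2e, of the lysine methyltransferase family, had 27647 bp from 23412466 to 23440112 on chromosome 5. Nr2f2, a nuclear receptor gene of veins and mesenchyme, had 25221 bp from 70345667 to 70370887 on chromosome 7.

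The triad gene Jph2 had 25482 bp on chromosome 2 from 163373529 to 163399010 (17204 bp in pool E and 17961 bp in pool F). Tnnt3, fast troponin T, shared 24733 bp on chromosome 7 from 142486780 to 142511512 with the neighbouring leukocyte gene Lsp1 (39150 and 22431 bp). Egfl7, a secreted factor of endothelium, had 23868 bp on chromosome 2 from 26569694 to 26593561 (24402 and 23517 bp). Widths rest on the joining of peaks: without it, 11 of the 12 genes had domains over 1.5 times narrower, and the widths ran from 4695 to 23209 bp, the latter at Nr2f2.

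Far from annotated TSSs most peaks were weak, and some of the strongest lay beside tRNA genes. In all, 15200 replicated peaks (36.2%) lay over 5000 bp from any TSS, with a median signal value of 4.69 and a median width of 563 bp. The highest signal value among them was 62.3, at an intergenic peak of 2110 bp on chromosome 14 from 76151621 to 76153730, 40730 bp from Nufip1 and within 1000 bp of the tRNA gene n-TEttc6. The next was 60.2, at a peak of 18999 bp on chromosome 15 from 85663691 to 85682689, over an exon, where the genes Gm49539 and Lncppara lie, and 52294 bp from a TSS of Ppara, a lipid-sensing nuclear receptor gene. A peak on chromosome 1 from 74816424 to 74817928 with a signal value of 59.7 lay 23061 bp from Wnt10a and within 1000 bp of n-TGgcc3. A peak on chromosome 12 from 8640056 to 8641774 with a signal value of 58.6 lay 32360 bp from Pum2. A peak on chromosome 13 from 21199104 to 21201217 with a signal value of 58.3 lay 9243 bp from Trim27 and within 1000 bp of n-TLcaa1. These tRNA genes come from the RefSeq annotation and were looked up after the peaks had been seen.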

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

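All tests in this part were chosen only after the result was seen. The replicated list held 2 peaks on chromosome Y although the animals were female; each of the other lists held 2 as well, and chromosome Y was outside the comparisons. The first peak, from 10643307 to 10643939, had a signal value of 13.2 and lay 200 bp from the pseudogene Gm20775. Male tissue in the pools is argued against, since 0 of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, active in most male tissues, were marked in any list. For the first peak, reads from elsewhere placed on Y sequence are a candidate explanation: sequence outside Y of at least 95% identity covered 98.6% of it, with the best match (98.7% over 624 bp) on chromosome 13 from 58402996 to 58403619, near Hnrnpk and Rmi1, where a replicated peak had a signal value of 63.3. For the second peak, from 90743975 to 90745114 with a signal value of 8.61 and 7943 bp from Mid1-ps1, such sequence covered 28.3%, between the 50% and the 10% set as bounds. Its best match outside Y (88.8% over 1085 bp) was on chromosome 7 from 7277653 to 7278704, where a replicated peak had a signal value of 47.5. That identity is below the 95% asked for, and the source of the second peak stays open. No biological explanation was tested.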

How the results depend on the processing

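The alternatives of a strict threshold in a single pool, of the pooled list for gene lists and all those for fast against slow fibre genes were chosen after the data had been seen. No paired analysis was possible because the technical numbers 1 and 2, shared by both pools, belong to libraries and the peak lists hold no value per library. The lower marking of X-linked genes passed its threshold under all 6 alternatives run (50.1 to 53.0% of X-linked genes), and the difference between fast and slow fibre genes under all 4 (6700.5 to 10319.5 bp). The share of peaks near a protein-coding TSS (41.3%) was 36.2% at 0 bp, 47.4% at 2500 bp, 46.5% with TSSs of all genes, 58.8% at a −log10 q-value of at least 10, 39.0% in the pooled list and 41.0 to 43.5% in the pools. The share of marked genes (69.3%) was 67.0% at 0 bp, 70.4% at 2500 bp and 67.2% at the strict threshold. The overlap of pool E peaks (82.5%) was 75.9% with 50% of the peak, 74.2% with 50% of both peaks, 84.4% at the strict threshold in both lists and 97.9% in pool E alone. That of pool F peaks (93.8%) was 92.7%, 79.6%, 98.6% and, in pool F alone, 99.8%. Lists marked less often numbered 1 against the background of the same CpG class (2 as reported), and lists with narrower domains 2 with joining over 3000 bp and 1 to 2 without a replicate (1 as reported). The cause was not tested, except that wider windows and looser overlaps count more by construction. Of 14 marking calls 4 were made under every setting (fast fibre, sarcomere and triad, endothelial, glycolysis), and of 14 width calls 9 (these 4 lists and the myogenic, fibroblast, muscle mass, housekeeping and neuron lists). Gained calls were germ cell genes less often at 0 bp, at the strict threshold and against the same CpG class. With that background the macrophage, smooth muscle, tendon and neuromuscular junction lists were marked more often. For width they were adipocyte genes without joining, limb position genes at 3000 bp, and cardiac genes (narrower) at 3000 bp and without replicate 2. Over single lists and genes, 584 values were the same, 215 moved, 22 calls were lost and 11 gained, and none reversed. Depth is unknown, so unmarked means not called here.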

Other observations

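The gene families and non-coding genes in this part, and the tests of CpG class, of CpG class and copies together and of tRNA genes, were chosen only after the results were seen. Gene families differed in how many members were marked in gastrocnemius, and in promoter CpG class; no enrichment was tested. Of 1135 olfactory receptor genes 4 (0.352%, 95% Wilson interval 0.137 to 0.903%) were marked: Olfr56, Olfr558, Olfr1033 and Olfr94. Of 327 vomeronasal receptor genes 1 was marked, Vmn1r4, of 57 keratin-associated protein genes 2, Krtap11-1 and Krtap16-1, and of 64 defensin genes 0. Low CpG promoters made up 99.7 to 100% of these families, and the shares of their CpG classes over all genes would have given 25.2 to 25.5% marked. Of the 39 Hox genes, which lay out the body axis, 38 were marked, all but Hoxd12, and of 83 ribosomal protein genes 81, all but Rpl10l and Rpl39l. Their CpG classes would have given 90.7% for the Hox genes (97.4% marked) and 96.6% for the ribosomal protein genes (97.6% marked). Of 19 Wnt genes 18 were marked, all but Wnt8a, and of 15 T-box genes 13, all but Tbx10 and Tbx19. The 44 collagen genes had 37 marked members (84.1%), with the widest domains at the fibrillar collagen genes Col1a1 and Col1a2 and the basement membrane genes Col4a1 and Col4a2. The clustered protocadherin genes had 41 of 55 marked with a median domain of 647 bp. Zinc finger genes named Zfp had 351 of 394 marked (89.1%), potassium channel genes 60 of 80 (75%) and interleukin genes 10 of 30 (33.3%). From CpG class 76.5, 72.6 and 27.5% would have been, and for the Wnt, T-box, collagen and protocadherin genes above 82.0, 73.5, 57.2 and 66.5%.

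Among lincRNA and antisense genes, Neat1, the scaffold RNA of paraspeckles, shared the widest domain with Frmd8os: 29164 bp on chromosome 19 from 5823352 to 5852515 (29931 bp in pool E and 23069 bp in pool F). Malat1, its neighbour and another abundant nuclear RNA, had 10788 bp. Carmn, a non-coding RNA of smooth muscle and heart, had 12440 bp (12967 and 12381 bp), Lncpint 10149 bp and Lockd 10355 bp (10409 and 3126 bp). The domain of 2310065F04Rik was 10893 bp wide (7131 and 10752 bp).

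X-linked genes were marked less often than autosomal genes (52.6 and 70.01%). CpG class and near-identical copies together may account only for the overall share among genes without a copy, since class differences in opposite directions offset each other. Genes with a copy were left out of that comparison. They were marked at 7.53% on X and 20.5% on the autosomes, without matching on CpG class. Of X-linked genes without a copy 63.6% were marked (95% Wilson interval 60.2 to 67.0%), against 63.4% expected from autosomal genes without a copy of the same CpG classes. By class, X-linked and autosomal genes without a copy were marked at 100 and 99.5% (high) and 32.6 and 27.6% (low), and the intermediate class had an odds ratio of 0.433 (two-sided Fisher's exact tests, adjusted p of 1, 0.0623 and 0.000319). A lower share was left in the intermediate class alone, where CpG class by itself (86.7% of all X-linked genes of that class against 94.3%) and copies by themselves (89.2% of those without a copy) are argued against as the whole cause. The inactive X of female cells is a candidate explanation for lower signal at X-linked promoters, not tested for marking. The escape genes Ddx3x (55.5), Eif2s3x (46.0), Kdm6a (54.7) and Pbdc1 (38.9), with Kdm5c left out because its value had been seen, had a median signal value of 50.3. Random lists were drawn from the 374 other marked X-linked genes of high or intermediate CpG class. The escape genes lay at percentile 99.64 of these lists (median 39.2) and at percentile 98.78 of lists matched on CpG class. The lists were not matched on how broadly genes are expressed, so the percentiles cannot tell escape from other traits of these 4 genes.

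Strong peaks far from TSSs numbered 261 at a signal value of at least 34.4, and their median CpG observed over expected ratio was 0.532, against 0.325 at the other 14939. Genes for tRNA may account for a part: 30 (11.5%) lay within 1000 bp of one, against at most 1 in the shuffles and 0.274% of the other distal peaks. RefSeq transcript starts lay near 65 (24.9%, against 5.88% of the others), and copies of TSS windows existed for 5 (1.92%), so none of the 3 covered most of these peaks, while 174 (66.7%) had none of them. The shares for tRNA genes and RefSeq starts lay between the bounds set for them, so reading them as partial sources was decided after the results were seen. Of the 403 annotated tRNA genes, 252 (62.5%) lay within 1000 bp of a replicated peak. That count took all replicated peaks, those near TSSs included, and has no shuffled share beside it. Among the distal peaks, 30 strong and 41 other peaks lay near a tRNA gene.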
